A study of Mus musculus with 6 samples.

How the data were processed

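HSCs from wild type and Chrm1-/- mouse bone marrow were profiled on 6 arrays, 3 per genotype, and samples were grouped by the genotype in the labels. Per the series design text, cells were sorted as Lineage-negative, Sca1+, cKit+ and Flt3-negative into lysis buffer, RNA was amplified with a NuGEN kit, and Affymetrix mouse gene ST arrays were hybridised at a core facility. Per the labels' protocols, RNA came from a column-based kit for small samples. Per the series design text, the authors processed the arrays in the Affymetrix analysis software, took fold changes and p-values from it and passed them to gene set enrichment analysis. The software's version, the summarization and the normalization are not given in the sources used here. The deposited table holds 1 value per transcript cluster and array, rounded to 2 decimals. The deposited values were taken as log2 signals from their range, since the table does not name a scale; the lowest value was 3.02 and the highest 13.67. Array medians between 6.49 and 6.57 and upper quartiles between 7.79 and 7.88 show that the columns were on a common scale, so they were used without further normalization. The labels do not say whether replicates are separate mice, so the p-values measure only the spread between these samples, which may be technical.

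Over all clusters, 5 of the 6 arrays correlated slightly better with the other genotype than with their own. The mean Pearson correlation of wild type replicate 1 was 0.925 within its group and 0.929 with the other group. Wild type replicate 3 had the lowest mean correlation with its own group, 0.918. No pair of arrays held the same values throughout, and all 6 arrays were kept as separate replicates.

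Of 41345 transcript clusters, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none there. Clusters with several or no symbols stayed out of the gene comparison. Identifiers of 23328 clusters matched a RefSeq gene table of GRCm38.p6, which was used for names and for which genes neighbour Chrm1; 0 symbols changed. The genome build of the array annotation is not stated, and no coordinates are given. For the 1082 genes with over 1 cluster, the cluster with the highest mean over the 6 arrays was used, which gave 22180 genes. Genes with a mean signal at or above the median of all genes, 6.77, were tested, 11094 in number.

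The groups were compared as Chrm1-/- minus wild type with limma 3.58.1 (lmFit and eBayes, 1 prior for all genes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are limma's moderated ones. A second count took unadjusted p under 0.05 with at least 1.5-fold, since array software reports unadjusted p and fold. Gene lists, 31 in number, were fixed with the test designs, the alternatives and the naming rule before the data were examined; 933 of their 1042 members were on the array. The 29 lists with at least 5 tested members went through camera with a preset correlation of 0.01, adjusted over the lists. The mean of a list's tested members on each array was also compared with limma, which gives the 95% intervals, and with an exact permutation test of the 6 values. Genes within 10 Mb of Chrm1 were tested with camera and Fisher's exact test.

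The text names Chrm1, then in each direction up to 12 genes. These were to be the largest changes past the adjusted threshold with non-overlapping groups. As none passed, they are the genes of smallest unadjusted p under 0.05 with at least 1.5-fold and no overlap, leaving out predicted genes, unnamed clones, receptor and antibody gene families and small RNAs. It also names members from the 4 of smallest unadjusted p in each list, and a fixed set of glucocorticoid, mobilization, stem cell, muscarinic and sex-linked genes. Ly6a, Ddx3y and Tsix of that set were not analysed here. One tested list and part of the fixed set are not reported here.

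Alternatives covered the filter on dim genes (none, or the 75th percentile), a further quantile normalization, median centring, the mean of all clusters of a gene, an intensity trend with robust moderation, no moderation, array weights, the replicate number as a block, leaving out each array, other thresholds, windows of 5 and 20 Mb, an estimated correlation in camera, fgsea 1.28.0 with 100000 permutations, and fry. All 10 splits of the arrays into 3 and 3 were refitted. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 joined the tables and drew the plots.

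The gene test was tested on simulated data with the means and spreads of these arrays, 11090 tested genes and 200 changed genes. Of 50 genes changed 1.5-fold it called 18%, of 50 changed 2-fold 50%, of 50 changed 4-fold 64% and of 50 changed 8-fold 66%. Genes were changed up or down, and those that then fell below the signal filter counted as not called. The share with an unadjusted p under 0.05 in limma was 84% at 2-fold and 70% at 8-fold. The shares at large folds thus also reflect the filter. Of 111 calls 12 were genes left unchanged. A simulated shift of the cell cycle list by -0.2 led to 1 list called, and simulated values with no shift led to 0 in camera. Each setting was drawn 1 time, with noise independent between genes. The simulation thus cannot show how often correlated members or effects of an array lead to false list calls.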

Results

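Gene expression was measured in haematopoietic stem cells (HSCs) sorted from the bone marrow of unchallenged mice. The cells carried no lineage markers, expressed Sca1 and the stem cell factor receptor Kit, and were negative for the cytokine receptor Flt3 at the surface. Wild type C57Bl/6 cells gave 3 arrays and cells lacking Chrm1, which encodes a muscarinic acetylcholine receptor, gave 3 arrays. The series concerns a route by which this receptor, acting in the brain through glucocorticoid hormones, prepares HSCs to leave the marrow. The one comparison in the design asks how HSCs that developed without the receptor differ from wild type at steady state. The deposited values are log2 signals with array medians from 6.49 to 6.57. The number of arrays limits the precision, and the median standard error of a difference between the groups was 0.17 on the log2 scale.

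Chrm1 itself gave a signal of 7.52 ± 0.13 (SD, n = 3) on the wild type arrays and 7.75 ± 0.35 (SD, n = 3) on the Chrm1-/- arrays. The Chrm1-/- arrays read 8.16, 7.52 and 7.58, so the transcript cluster used for the gene was not lower in the knockout. A further Chrm1 cluster read 5.74 in wild type and 5.70 in Chrm1-/-. Which part of the gene the probes cover, and which part was deleted, are not given in the sources used here, so these levels check nothing about the labels. The muscarinic receptor genes Chrm2, Chrm3, Chrm4 and Chrm5 had mean signals between 5.86 and 6.58 in both groups, below the signal needed for testing.

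Of the genes that bear on the sort, Kit read 10.90 ± 0.05 (SD, n = 3) in wild type and 10.88 ± 0.10 (SD, n = 3) in Chrm1-/-, and Cd34, a sialomucin of stem and progenitor cells, read 11.24 and 11.30. Flt3, against whose protein the cells were sorted, had transcript signals of 9.99 ± 0.11 (SD, n = 3) and 10.17 ± 0.19 (SD, n = 3). Its mean signal lay at percentile 93.3 of all genes, so the transcript signal was high in cells sorted as lacking the protein. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 7.89 or more on all 6 arrays, while Xist, the RNA that silences an X chromosome in female cells, lay between 5.06 and 5.42 on all 6. Kdm5d was the one of these with an unadjusted p under 0.05, at 9.78 in wild type and 9.18 in Chrm1-/-, a log2 difference of -0.60 ± 0.24 (SE). Of 11 tested housekeeping genes, 0 had an unadjusted p under 0.05 in limma, also after the adjustment, and their median difference was 0.04. Rplp0 stood apart among them at -1.32 ± 0.68 (SE).

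Genes of the cell division cycle were lower in Chrm1-/- HSCs as a list in camera, a call that was lost with an estimated correlation, by list means and without 1 of the arrays. Of 53 tested members of the cell cycle list, 38 had a lower and 14 a higher mean signal in Chrm1-/-, and the list's median log2 difference was -0.15. Birc5, which encodes the mitotic and anti-apoptotic protein survivin, read 8.61 ± 0.27 (SD, n = 3) in wild type and 7.74 ± 0.19 (SD, n = 3) in Chrm1-/-, a difference of -0.87 ± 0.18 (SE). Nuf2, a component of the kinetochore complex that binds spindle microtubules, differed by -0.79 ± 0.18 (SE), Mcm4, a subunit of the replicative helicase, by -0.66 ± 0.23 (SE), and Top2a, the topoisomerase that untangles chromosomes before division, by -0.26 ± 0.10 (SE). These 4 genes had an unadjusted p under 0.05, and the 3 Chrm1-/- arrays lay below the 3 wild type arrays for each of them.

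The cell cycle list was the one list of 29 tested that passed, falling relative to other genes with an adjusted p of 0.00148 in limma's camera. The call was lost with an estimated correlation in camera, at an adjusted p of 0.218. That estimate, -0.013, lay below the preset 0.01, so a higher correlation among members did not end the call. In limma 0 single members passed, over all genes or adjusted over the list alone. Preranked enrichment with fgsea gave the list an adjusted p of 0.00057, and fry, which tests a list against no change and not against other genes, gave 0.0471. The mean of the list's members on an array was 9.25 ± 0.03 (SD, n = 3) in wild type and 9.10 ± 0.04 (SD, n = 3) in Chrm1-/-, and the difference of -0.15 had a 95% interval from -0.26 to -0.04. On this single value per array, the two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The 7 members whose groups did not overlap all lay lower in Chrm1-/-. They made up 13.2% of the list, where chance gives 10% and all tested genes gave 5.79%. Leaving out Chrm1-/- replicate 2 ended the camera call, with a median of -0.13; over the 6 fits that left out 1 array the adjusted p ran from 0.00465 to 0.11. The test of list means in limma, chosen after seeing the data, gave an adjusted p of 0.457.

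**Figure D1:**
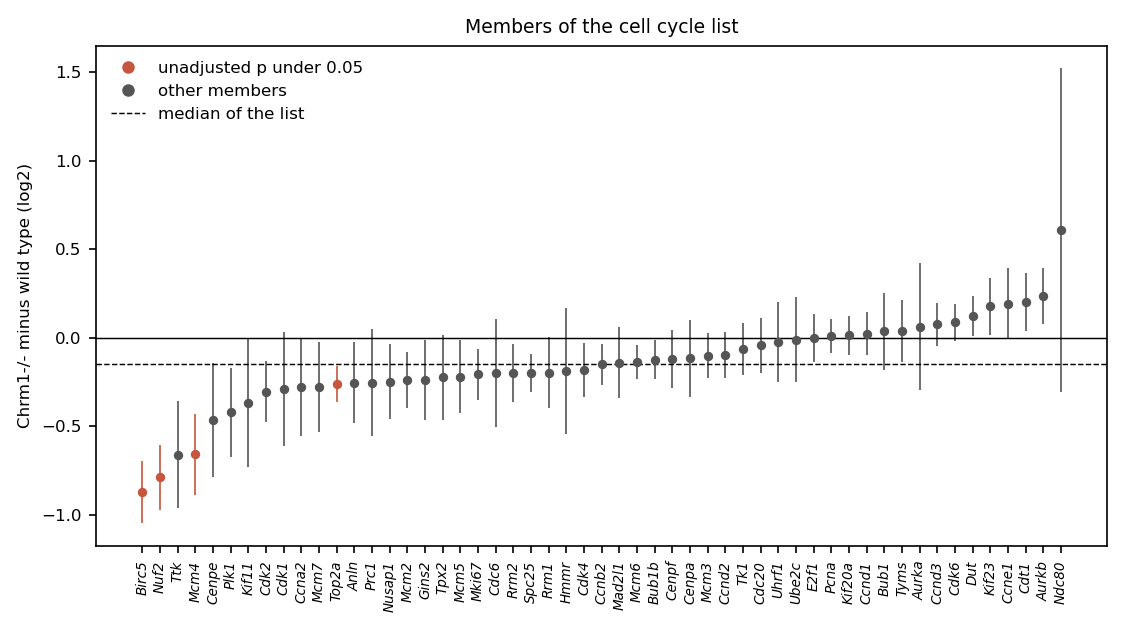
Log2 difference between Chrm1-/- and wild type for each of the 53 tested members of the cell cycle list, ordered by size, with points for the fitted difference and bars for its standard error (3 arrays per group). The dashed line marks the list's median of -0.15, and 38 members lie below 0.

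Genes linked to quiescence, the resting state of most HSCs, included 2 with an unadjusted p under 0.05, both higher in Chrm1-/-, and 0 that passed in limma over all genes or adjusted over the list alone. Btg2, an antiproliferative gene, read 8.82 ± 0.47 (SD, n = 3) in wild type and 9.96 ± 0.08 (SD, n = 3) in Chrm1-/-. Cdkn1b, an inhibitor of cyclin-dependent kinases, read 8.40 ± 0.26 (SD, n = 3) and 9.02 ± 0.28 (SD, n = 3). Cdkn1c, a related inhibitor, had a difference of -0.31 ± 0.17 (SE), and Foxo4, a transcription factor of the same list, one of -0.40 ± 0.23 (SE). Of the 25 tested members 18 were higher, and the list as a whole did not pass in camera, with an adjusted p of 0.327 and a mean difference of 0.14 (95% interval -0.07 to 0.36). That difference leaned on wild type replicate 3. Less its mean over all arrays, the list lay at -0.05, 0.11 and -0.28 on the wild type arrays. On the Chrm1-/- arrays it lay at 0.06, 0.14 and 0.01.

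Marker lists of other blood cells, most of which the gates of the sort are meant to remove, did not pass either. Granulocyte precursor markers leaned the same way as the cell cycle list, with 6 of 8 tested members lower and a mean difference of -0.17 (95% interval -0.37 to 0.02). The list's median was -0.12 over these 8 and -0.06 over the 22 on the array with no filter on dim genes. Centred on its mean over all arrays, it lay at 0.04, 0.09 and 0.13 on the wild type arrays. The Chrm1-/- arrays lay at 0.09, -0.265 and -0.08, so the difference leaned on Chrm1-/- replicate 2 and replicate 1 did not share it. The serine protease gene Ctsg of granule-forming precursors differed by -0.44 ± 0.21 (SE) and Elane, which encodes neutrophil elastase, by -0.36 ± 0.24 (SE). Camera gave this list an adjusted p of 0.315, and the list passed on leaving out Chrm1-/- replicate 1. Erythroid markers had 9 of 13 members higher, a mean difference of 0.11 (95% interval -0.12 to 0.34) and an adjusted p of 0.501 in camera. Less its mean over all arrays, the erythroid list lay at 0.07, -0.001 and -0.23 on the wild type arrays. On the Chrm1-/- arrays it lay at 0.23, -0.10 and 0.03, so the difference leaned on wild type replicate 3. Markers of multipotent and lymphoid-primed progenitors had a mean difference of 0.01 (95% interval -0.15 to 0.16). One member of that list, Cd52, a surface glycoprotein of lymphocytes, read 8.13 ± 0.19 (SD, n = 3) in wild type and 8.89 ± 0.11 (SD, n = 3) in Chrm1-/-. Cd52 passed when adjusted over the list alone and did not pass over all genes. The platelet gene Pf4 differed by -0.88 ± 0.37 (SE), while F2rl2, a thrombin receptor family gene of the same megakaryocyte list, differed by 1.13 ± 0.36 (SE). The macrophage gene Cd68 differed by -1.07 ± 0.39 (SE). Among HSC markers, Procr, the surface receptor used to purify HSCs, read 8.45 ± 0.05 (SD, n = 3) in wild type and 8.20 ± 0.04 (SD, n = 3) in Chrm1-/-, and the list had 12 members higher, 13 lower and a mean difference of 0.01 (95% interval -0.11 to 0.13).

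Genes that respond to glucocorticoids did not pass as a list. Of 24 tested response genes 15 were higher and 9 lower, the mean difference was 0.10 (95% interval -0.02 to 0.23), and camera gave an adjusted p of 0.327. The median was 0.06 over these 24, 0.005 over the 36 on the array with no filter on dim genes and 0.02 over the 11 past the 75th percentile. The 3 Chrm1-/- list means lay above the 3 wild type ones, a two-sided exact permutation p of 0.1. Acer2, an alkaline ceramidase, read 6.95 ± 0.32 (SD, n = 3) in wild type and 8.01 ± 0.26 (SD, n = 3) in Chrm1-/-, and Zbtb16, a zinc finger transcription factor, read 6.73 ± 0.17 (SD, n = 3) and 7.25 ± 0.24 (SD, n = 3). Those 2 genes had unadjusted p under 0.05, and 0 members passed in limma over all genes or adjusted over the list alone. The classical responders moved little, with differences of 0.03 ± 0.14 (SE) for Fkbp5, 0.06 ± 0.12 (SE) for Tsc22d3 and 0.17 ± 0.11 (SE) for Per1. Nr3c1, the glucocorticoid receptor, differed by 0.13 ± 0.26 (SE). The list of the receptor and its cofactors had a mean difference of 0.03 (95% interval -0.10 to 0.17), with the co-chaperone Stip1 at -0.29 ± 0.12 (SE). Stip1 also lies within 10 Mb of Chrm1, among the neighbours compared below.

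Genes of the actin cytoskeleton and of adhesion and homing bear on the movement of HSCs, and neither list passed in camera. Actin genes had 37 of 68 members higher and 30 lower, with a mean difference of -0.01 (95% interval -0.11 to 0.10), so that a shift of the list beyond 0.11 in either direction lies outside the interval. Tpm4, a tropomyosin, differed by 1.05 ± 0.42 (SE), with wild type arrays at 9.53, 9.42 and 8.09 and Chrm1-/- arrays at 10.39, 9.70 and 10.09. Brk1, a subunit of the actin-nucleating WAVE complex, differed by -0.75 ± 0.34 (SE). Adhesion and homing genes had a mean difference of 0.01 (95% interval -0.10 to 0.12). Within that list Alcam, an adhesion molecule of the immunoglobulin superfamily, read 9.11 ± 0.05 (SD, n = 3) in wild type and 9.59 ± 0.08 (SD, n = 3) in Chrm1-/-, the tetraspanin gene Cd151 differed by 0.66 ± 0.20 (SE) and the integrin chain gene Itgb2 by -0.47 ± 0.16 (SE). Cxcr4, the receptor that holds HSCs in the marrow, read 11.09 ± 0.29 (SD, n = 3) and 11.30 ± 0.27 (SD, n = 3). Csf3r, the receptor for the mobilizing cytokine G-CSF, differed by 0.09 ± 0.14 (SE). Of these lists, 0 members passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05.

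**Figure D2:**
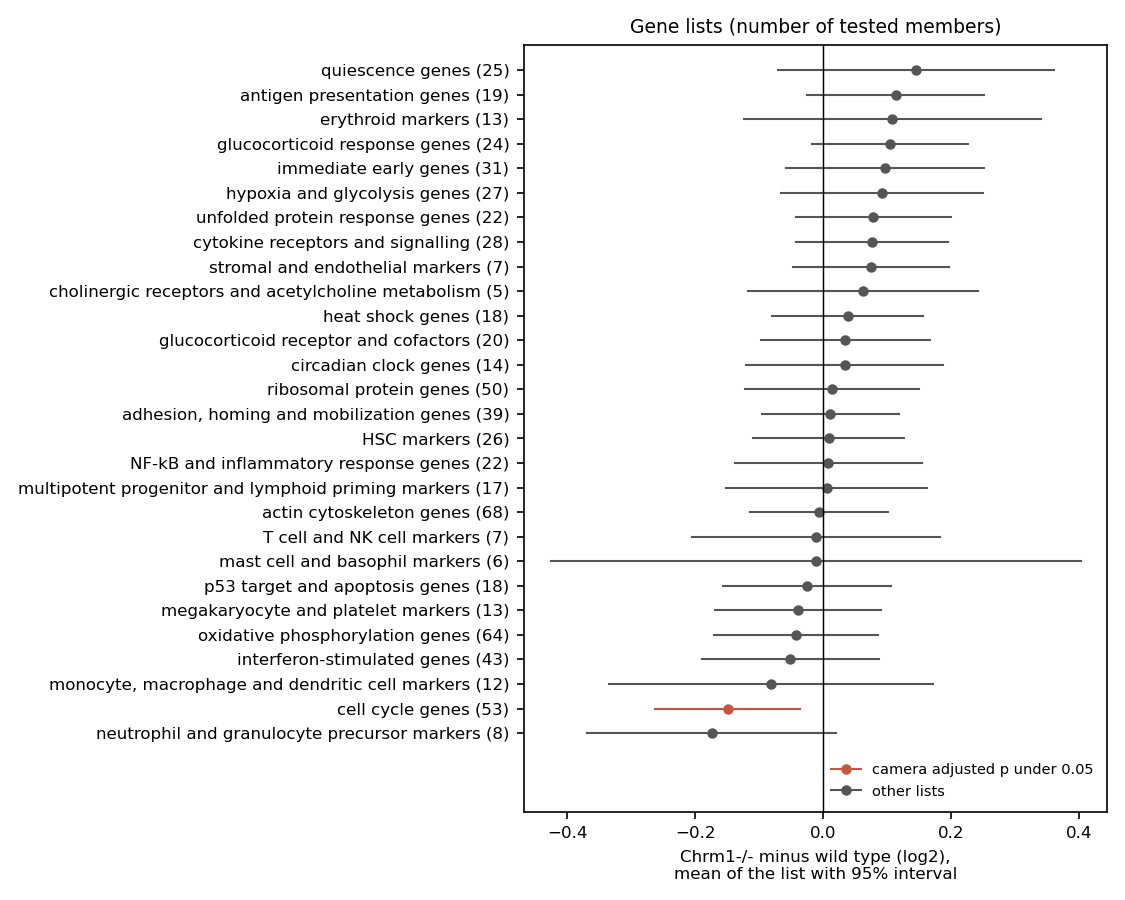
Mean log2 difference between Chrm1-/- and wild type for gene lists, with the number of tested members in brackets and lines for 95% intervals from the 6 array means of each list. The cell cycle list, in colour, has a mean of -0.15 and an interval below 0, while the intervals of the other lists shown include 0. The intervals are not adjusted for the number of lists, and limma's test of list means gave the cell cycle list an adjusted p of 0.457.

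**Figure D3:**
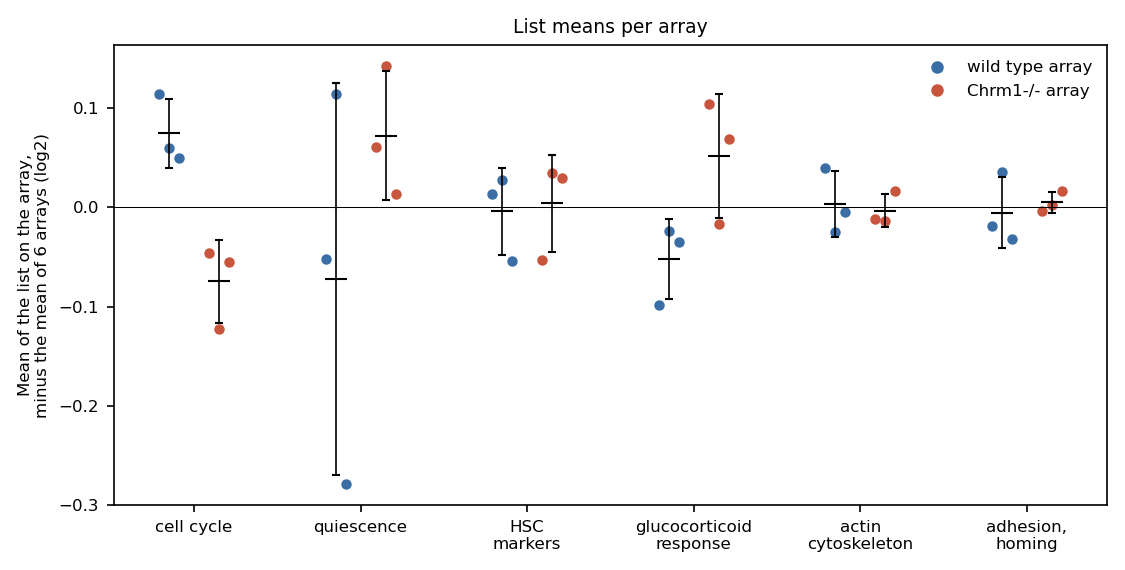
Mean signal of 6 gene lists on each array, less the mean of that list over the 6 arrays, in log2 units; points are arrays and bars the mean with SD of 3 arrays. The Chrm1-/- points lie below the wild type points for the cell cycle list and above them for the glucocorticoid response list.

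Other lists stayed within the spread between arrays. By camera p, antigen presentation genes came next after the cell cycle list, with 17 of 19 members higher, among them the class II gene H2-Ab1 at 0.39 ± 0.18 (SE). Their mean difference was 0.11 (95% interval -0.02 to 0.25) and the adjusted p in camera 0.135, and the list passed on leaving out Chrm1-/- replicate 1. Immediate early genes had 24 of 31 members higher and a mean difference of 0.10 (95% interval -0.06 to 0.25). Less its mean over all arrays, that list lay at -0.14, 0.002 and -0.01 on the wild type arrays. On the Chrm1-/- arrays it lay at -0.05, 0.04 and 0.15. Interferon-stimulated genes had 29 of 43 members lower and a mean difference of -0.05 (95% interval -0.19 to 0.09). Respiratory chain genes had 39 of 64 members lower, with Ndufa2 of complex I at -0.38 ± 0.15 (SE), and an adjusted p of 0.327. Cytokine receptor genes, with Stat5a at 0.34 ± 0.14 (SE), and unfolded protein response genes, with the chaperone gene Dnajb9 at 0.51 ± 0.17 (SE), had mean differences of 0.08 each. Among inflammatory genes the chemokine Ccl3 read 7.24 ± 0.16 (SD, n = 3) in wild type and 7.86 ± 0.23 (SD, n = 3) in Chrm1-/-, while the list's mean difference was 0.01. Hypoxia and glycolysis genes had a mean difference of 0.09, with the muscle-type phosphofructokinase gene Pfkm at 0.32 ± 0.11 (SE). The remaining lists, for p53 targets, heat shock, ribosomal proteins, the circadian clock, cholinergic receptors, mast cells, monocytes, T and NK cells, megakaryocytes, and stroma and endothelium, had mean differences between -0.08 and 0.07. Of B cell markers 4 genes were tested, too few for a list test. Median, mean and camera direction differed in sign for the HSC, actin, adhesion, heat shock, ribosomal protein, mast cell, monocyte and p53 target lists, whose camera adjusted p values were 0.814 or more.

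The single genes named in each direction by unadjusted p, fold and separation served varied functions. None passed the adjusted threshold, each with an adjusted p of 0.996 in limma. Among the 12 named as higher in Chrm1-/-, Tmem253 read 6.68 ± 0.19 (SD, n = 3) in wild type and 7.85 ± 0.24 (SD, n = 3) in Chrm1-/-. Cnn3, an actin-binding calponin, differed by 0.84 ± 0.12 (SE). Ube2n, a ubiquitin-conjugating enzyme of immune signalling, differed by 0.93 ± 0.15 (SE), Zc3h12c, a zinc finger gene, by 0.84 ± 0.14 (SE), and Sh2b3, the adaptor Lnk that restrains cytokine signalling in HSCs, by 0.66 ± 0.13 (SE). Erdr1 differed by 1.53 ± 0.24 (SE) in the cluster of higher signal and by 0.49 in its other cluster. Gdpd3, a phosphodiesterase of lipid metabolism, had the largest difference of the 12, at 3.30 ± 0.74 (SE), with wild type arrays at 8.53, 5.98 and 5.67 and Chrm1-/- arrays at 10.06, 10.25 and 9.78. Zfp992 differed by 1.96 ± 0.48 (SE) and Spty2d1 by 0.92 ± 0.19 (SE).

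None of the 12 named as lower passed the adjusted threshold either. Among them Tmem29 had the largest difference, at -1.79 ± 0.36 (SE), in the cluster of higher signal, and its other cluster differed by -0.05. Ing5, a subunit of histone acetyltransferase complexes, differed by -1.50 ± 0.36 (SE), and Med9, a Mediator subunit, by -1.01 ± 0.25 (SE). Ada, adenosine deaminase, read 9.22 ± 0.28 (SD, n = 3) in wild type and 8.29 ± 0.22 (SD, n = 3) in Chrm1-/-. Crbn, the substrate receptor of a ubiquitin ligase, differed by -0.64 ± 0.13 (SE), Rhot2, a mitochondrial GTPase, by -0.67 ± 0.15 (SE), the sorting nexin gene Snx13 by -0.94 ± 0.18 (SE), Trappc13 of a vesicle tethering complex by -0.92 ± 0.22 (SE) and the collagen gene Col10a1 by -0.75 ± 0.17 (SE). Tceanc2 was lower in both of its clusters, by -0.69 and -0.90.

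**Figure D4:**
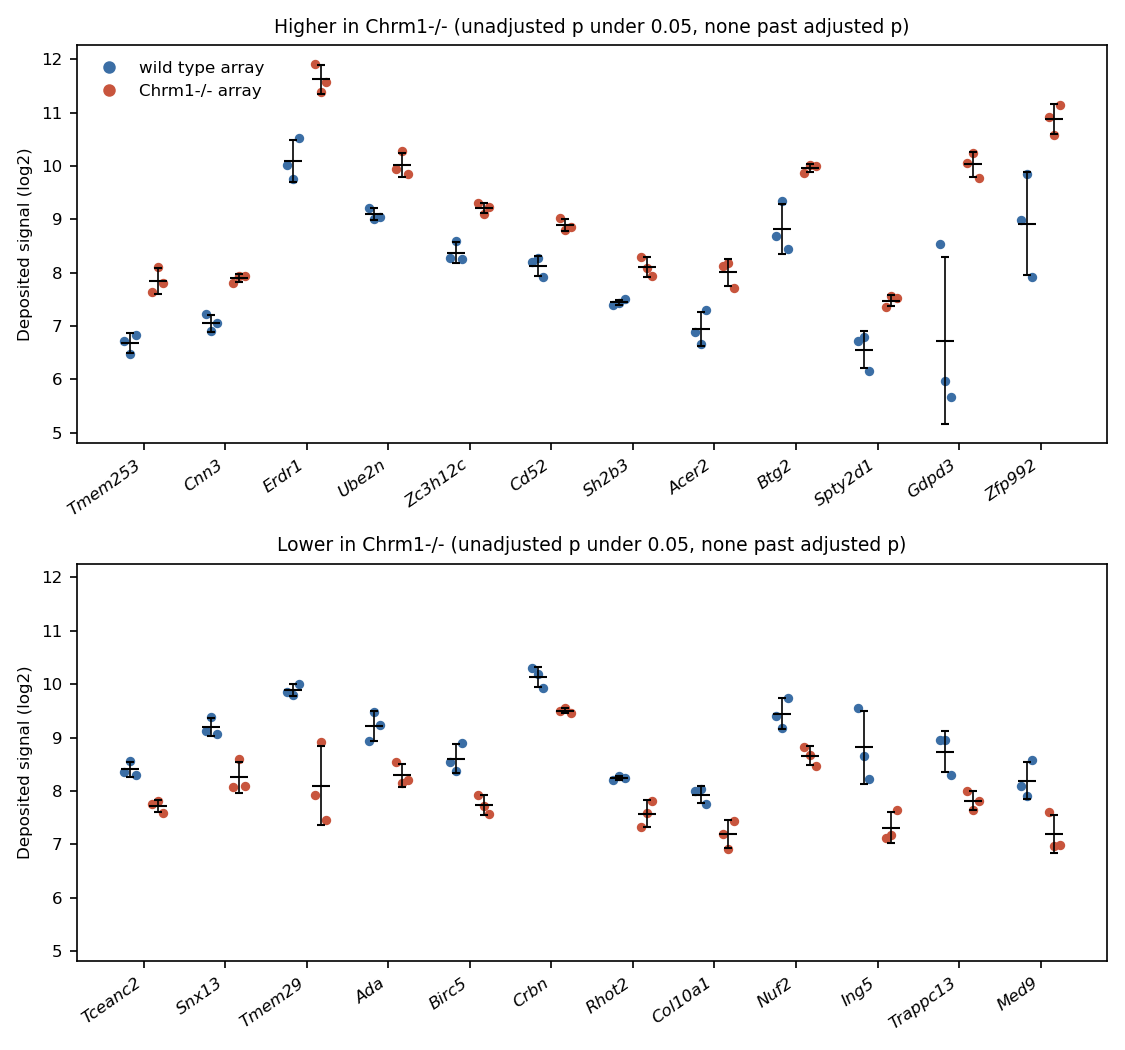
Deposited log2 signal on each array for the 12 genes named as higher and the 12 named as lower in Chrm1-/-, with points for arrays and black bars for the mean with SD of 3 arrays. The groups do not overlap for any of the 24 genes, by the rule that chose them, and Gdpd3 spans 5.67 to 8.53 in wild type.

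Across the 11094 genes tested, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.926. At an unadjusted p under 0.05 there were 332 genes, 155 higher and 177 lower, where chance alone gives 555; on leaving out 1 array the number ran from 335 to 522, the highest without wild type replicate 3. Those that also differed at least 1.5-fold numbered 149, 70 higher and 79 lower. Their balance shifted with single arrays, to 70 higher and 173 lower without wild type replicate 3 and to 124 higher and 76 lower without wild type replicate 1. Groups did not overlap for 642 genes, 5.79% of those tested, where chance gives 10%. The two-group test without moderation called 1 gene, Apmap, at -0.51. Leaving out wild type replicate 1 let Gdpd3 pass at 4.21, and leaving out Chrm1-/- replicate 3 let the small nucleolar RNA gene Snord49a pass at -3.08; Apmap and Snord49a are named after their values were seen.

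Genes that neighbour Chrm1 on chromosome 19 did not pass as a group. A knockout allele made in cells of another mouse strain can carry flanking sequence of that strain. Such sequence could raise some neighbours and lower others, and a median or camera would miss changes of both signs. Fisher's exact test counts neighbours changed in either direction but rests on few genes, so flanking sequence stays open. The 200 tested genes within 10 Mb of Chrm1 had a median difference of 0.00 and a camera p of 0.874 from limma. Of these, 8 genes had an unadjusted p under 0.05, which is 4% against 2.97% of the other genes, a two-sided Fisher's exact p of 0.397. On leaving out 1 array their number ran from 5 to 14, the highest without Chrm1-/- replicate 1. Dnajc4 at -1.52 ± 0.39 (SE), Rab1b at 1.19 ± 0.37 (SE) and Naa40 at -0.98 ± 0.27 (SE), named after their values were seen, were among them.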

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

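The tests in this part were chosen only after the results were seen. Among 5621 bright transcript clusters that carry no gene name in the annotation, and so lay outside the gene comparison, 1 passed limma's adjusted threshold, and 224 had an unadjusted p under 0.05. This cluster, with the array identifier 17207489, read 4.84, 4.69 and 4.84 on the wild type arrays and 10.43, 9.68 and 9.53 on the Chrm1-/- arrays. The wild type values lie below the lower quartiles of those arrays, 5.32 to 5.38, and signal over background was not analysed here, so the difference is one between signals and not a measured fold. The difference in signal was 5.09 ± 0.28 (SE) on the log2 scale, with a limma adjusted p of 0.0248 over the unnamed clusters and 0.0358 when the tested genes were added. The adjusted p was 0.0741 over all unnamed clusters without the filter on dim ones. Leaving out 1 array kept it past the threshold without Chrm1-/- replicate 1 (0.0238) or replicate 3 (0.0462). The call was lost without Chrm1-/- replicate 2 (0.151) and without wild type replicate 1 (0.318), 2 (0.192) or 3 (0.169), while the difference in signal, with the same limit, lay between 4.82 and 5.26 on leaving out any 1 array. Its gene, and its place in the genome relative to Chrm1, were not analysed here, and no explanation for it was tested. Of 925 tested clusters with several gene symbols, 0 passed in limma and 23 had an unadjusted p under 0.05.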

How the results depend on the processing

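The test of list means was chosen after seeing the data. Further quantile normalization, median centring, cluster averaging, filter removal, trend with robust moderation and array weights kept the call of the cell cycle list. With no filter, where more genes were tested, 567 genes had an unadjusted p under 0.05 in place of 332. Genes past the adjusted threshold numbered 1 with no moderation and from 0 to 1 on leaving out 1 array. Genes past unadjusted p and 1.5-fold numbered 149, against 84 with the filter at the 75th percentile, where fewer genes were tested, 66 with no moderation, 41 at 2-fold, 41 at an unadjusted p under 0.01, and 176 to 244 on leaving out 1 array, the highest without Chrm1-/- replicate 1 or wild type replicate 3 (243); without Chrm1-/- replicate 2 it was 224. Lists past the threshold numbered 0 with an estimated correlation, 0 by list means, and 0 to 3 on leaving out 1 array. The cell cycle median was -0.15 with an estimated correlation (adjusted p 0.218), the mean -0.15 by list means (0.457), and the median -0.17 to -0.10 on leaving out 1 array, with adjusted p from 0.00465 to 0.11. On leaving out 1 array the neutrophil list's median ran from -0.192 to -0.0442, that of antigen presentation from 0.05 to 0.13 and that of glucocorticoid response from 0.01 to 0.09. Except where stated, the cause was not tested.

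Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.03, 0.01 and -0.01. With the replicate block, 0 genes passed the adjusted threshold (396 at an unadjusted p under 0.05), 209 passed unadjusted p and 1.5-fold, and 1 list passed, the cell cycle list at a median of -0.15, while its DNA replication part lost its call. The sign of an uncalled value turned in 70 of all 514 list alternatives run, 23 of all 2096 gene alternatives, and 0 of 352 for the 24 genes chosen by p, fold and separation. For those 24 genes the separation rule itself prevents a turned sign on leaving out 1 array, so the 0 is no measure of stability. Signal over background was not analysed here, so dim genes are limited by an unknown floor.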

Other observations

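The second cell cycle list, the mitosis and DNA replication parts of the first list, the comparison with lists of like signal and the comparison of progenitor markers were chosen only after the cell cycle result was seen. The outcome that would argue against the progenitor markers was narrowed after their values were seen. The mitosis members of the list had 23 of 29 genes lower and a median of -0.20, with a camera p of 3.39e-05 from limma, and the DNA replication members had 12 of 18 lower and a median of -0.12, with a camera p of 0.0475. With an estimated correlation these p values were 0.00937 and 0.0987. The DNA replication call was also lost with fgsea, after a further quantile normalization and in each of the 6 fits that left out 1 array, over which its median ran from -0.12 to -0.06.

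A further list of cell cycle genes that shares none with the first, covering kinesins, condensins, replication factors and checkpoint genes, had 59 of 83 tested genes lower and 23 higher. Its median was -0.17 and its mean difference -0.19 (95% interval -0.29 to -0.08), and camera in limma gave p = 6.54e-07, or 0.00861 with an estimated correlation. Less its mean over all arrays, the list lay at 0.15, 0.11 and 0.02 on the wild type arrays and at -0.15, -0.07 and -0.06 on the Chrm1-/- arrays, a two-sided exact permutation p of 0.1.

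The lower cell cycle signal was weighed against technical explanations. A shift of all genes of like brightness is argued against, since 0% of 10000 random lists matched on mean signal had a median as low as -0.15, and their lower 2.5% limit was -0.07. A peculiarity of the fixed list is argued against by the second list, with a camera p of 6.54e-07. One array alone as the source of the call stays open for the first list. That call held in 5 of 6 fits that left out 1 array. It was lost without Chrm1-/- replicate 2, where the median moved from -0.15 to -0.13. One array alone as the source of the lower signal, a question apart from the call, is argued against. For the first list no outcome on this was fixed beforehand. Less its mean over all arrays, the first list lay at 0.11, 0.06 and 0.05 on the wild type arrays. On the Chrm1-/- arrays it lay at -0.05, -0.12 and -0.06. Its median stayed between -0.17 and -0.10 on leaving out any 1 array. For the second list all 6 fits that left out 1 array kept camera p under 0.05. Fewer granulocyte, erythroid or lymphoid-primed progenitors in the Chrm1-/- sorts, cells that the Sca1 and Flt3 gates are meant to remove, stay open. Their marker lists had mean differences from -0.17 for granulocyte precursors to 0.11 for erythroid cells, with intervals that include 0. The erythroid value leaned on wild type replicate 3, and the granulocyte value on Chrm1-/- replicate 2, where each list was lowest. Whether the sorted cells held unlike shares of multipotent progenitors was not tested. The list that holds their markers had 8 of 17 tested members higher and 8 lower, with Cd48 at -0.38 ± 0.22 (SE) and Cd34 at 0.06 ± 0.11 (SE). Whether fewer Chrm1-/- HSCs were dividing was not tested, and no measurement of dividing cells was used here.

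With 10 splits of the arrays, the share of splits with a result as large cannot go under 0.1. For the camera p of the cell cycle list, 1 split, the real one, was as small, at 5.09e-05, and the nearest other split gave 0.0557. For gene lists past the threshold the real split gave 1 and the highest other 1, with 3 splits giving as many. For genes past the adjusted threshold the real split gave 0 in limma (332 at an unadjusted p under 0.05) and the highest other 1, with all 10 giving as many. For genes past unadjusted p and 1.5-fold the real split gave 149 and the highest other 253, with all 10 giving as many. The real split thus had the fewest such genes of the 10, and 332 at an unadjusted p under 0.05, where the others had 373 to 592.

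The first principal component of the tested genes, with 26.6% of the variance, set wild type replicate 3 at 37.4 against -12.2 to 1.53 for the other arrays. The second, with 21.3%, set Chrm1-/- replicate 3 at -32.6 against -3.34 to 14.1. Neither component separated the genotypes.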
